A study of Arabidopsis thaliana with 4 samples.

How the data were processed

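RNA from 4 untreated Col-0 rosette cores was sequenced. Per the labels' protocols, seeds had a cold treatment at 4 °C and plants grew at 22 °C with 16 h of light at 100 µE per m2 and s, total RNA was depleted of ribosomal RNA with a plant leaf kit, and libraries were made with a strand-specific Ion Torrent kit and sequenced on an Ion Proton. Per the submitters' processing notes, Torrent Suite 4.0.2, HTSeq and TAIR10 were used. The aligner and the settings of the counting are not given in the sources used here. The deposited values are raw counts, whole numbers with 1 row per TAIR10 transcript model, with no normalization by the authors.

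The table held 40745 rows for 32678 loci, of which 26795 have 1 transcript model and 5883 have several. Protein-coding genes with 1 model had a median mean count of 55.5, those with 2 models 0.5 and those with at least 3 models 0.25. Rows of genes with several models held 1.67 ± 0.0409% of the counts (SD, n = 4). For this reason every value comes from nuclear genes with 1 model (26516 genes, 20912 of them protein-coding), a restriction the design fixed before the data were examined had not foreseen, and organelle shares from all genes with 1 model. Of 425 list genes in the table, 111 have several models and were left out, among them CCA1, LHY, FLC, SVP, RBCS1A, ACT2 and UBQ10. AOP2 was not analysed here. Genes whose exons overlap a gene of the opposite strand over more than 20% of their length are marked where named, because opposite-strand genes that cover each other had near-equal counts. No organelle locus matched the reference used here, so organelle genes have no names, and the alternative without ribosomal and transfer RNA genes was not run for them.

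Gene names, exon lengths and coordinates come from the NCBI annotation of the TAIR10.1 assembly, in which 31912 loci matched. Coordinates are 1-based. Symbols that this annotation lacks, or that more than 1 locus shares, were replaced by the locus identifier where such genes are named.

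CPM are computed on the nuclear 1-model counts after TMM scaling, here from the deposited counts. A total of 12771 genes passed edgeR's filter for 1 group (minimum count 10, scaled from the median library to each library's size), which asks for the minimum in all 4 libraries and so leaves out genes low in any. Variation beyond counting noise was tested per gene with a chi-square test of Poisson heterogeneity given TMM library sizes, adjusted by Benjamini-Hochberg, with a threshold of 0.05. Variation beyond genes of the same level was tested with edgeR's quasi-likelihood fit of an intercept, robust, one-sided. Gene list levels are medians of log2 CPM per kb of exon, set as a percentile among 10000 random lists of nuclear protein-coding genes. List variability and list shifts were set against 10000 random lists matched on expression in 20 bins. Gene pairs were tested with limma on the log2 ratio within each library after adding a prior count of 0.5 and dividing by exon length, for pairs with at least 10 counts summed over the libraries in each gene. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

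Library totals ran from 5639486 to 7692788 counts, and 3 counts, the limit that a count of 0 allows, equal 0.409 to 0.561 CPM. Intervals on shares are 95% exact binomial intervals. In simulated data of 12771 genes, the changed genes were raised in 2 of the 4 libraries, drawn at random for each gene. The test of counting noise recovered 68% of those raised 1.5-fold, 98% at 2-fold and 100% at 4-fold and 16-fold, with 8 false calls. The edgeR test recovered 0% at any of these fold sizes with the gene-specific scatter of these libraries, and 42%, 94%, 100% and 100% when all genes had 1 low dispersion. The pair test recovered 50 of 50 pairs made to differ 2-fold, with 3 false calls among 50, under normal noise of SD 0.25 per gene. In the tested pairs the SD of the log2 ratio over libraries ran from 0.118 (PSBO1 over PSBO2) to 2.92 (PR1 over PDF1.2). Recovery may thus be lower for pairs of wide spread. Of 500 random lists, 19 fell outside the central 95%.

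The rule for named genes, fixed before the data were examined, takes the 10 nuclear genes of highest mean CPM, the 12 called genes of at least 5 CPM with the largest ratio of quasi-dispersion to trend, the 2 highest and 2 lowest members of each list per kb, both genes of each pair, and the highest organelle genes. As no gene was called, the 12 were taken by the same ratio. List members named for their values per core, and LFY, LAS, AP3, FRO2, NRT2.1, MYB36, TMM, PXY, CLV1, KNAT1, PR1, YLS8, MAX4 and HB21 where the rule does not name them, were chosen after their values were seen. The fixed lists are the 23 named in the results: meristem and boundary, strigolactone and bud, floral transition, floral organ, photosynthesis, cell cycle, secondary wall, phloem and cambium, epidermis and stomata, root, pollen, seed maturation, clock, salicylic acid, jasmonate, touch response, heat shock, cold and drought, senescence, glucosinolate, gibberellin, cytokinin and reference genes. Alternatives tried were DESeq2 size factors or library totals in place of TMM, no filter or a mean of at least 5 CPM, organelle genes included, no length term, other prior counts, other count minimums, and leaving out each library. Added after seeing the data were all rows as deposited, overlapping genes left out, the list shifts with their alternatives, and list levels without each library.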

Results

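The transcriptome of the centre of the Arabidopsis rosette, which holds the shoot apex and the bases of the youngest leaves, was measured by RNA sequencing in 4 untreated cores of the accession Col-0. The cores were the central 1.5 to 2 cm of rosettes of 31-day-old plants grown in 16-h days at 22 °C. All 4 libraries belong to 1 group, so the design implies a description of this tissue and of how far its replicates differ, with no contrast between treatments. The libraries, called core 1 to core 4, held 7692788, 6821456, 6998463 and 5639486 counts, a mean of 6788048 ± 853061 (SD, n = 4). Nothing in the labels says that the cores came from separate plants. Every p-value that compares libraries thus speaks only of the spread between these samples, which may be technical. Fisher's exact test below takes gene pairs as its units instead.

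Genes with several transcript models, among them RBCS1A, could not be ranked here. The most abundant transcript of nuclear genes with 1 model was LHCB1.3 (AT1G29930, TAIR10.1 reference, chromosome 1, 10477885 to 10479114, plus strand). This gene encodes a chlorophyll a/b-binding protein of the light-harvesting complex. It had 23404 ± 4431 CPM (counts scaled to a library of 1e6; SD, n = 4) and took 2.25% of the counts on genes with 1 transcript model. PRXR1, a peroxidase gene (AT4G21960, chromosome 4, 11646109 to 11648644), followed with 9993 ± 2409 CPM, and TCTP, a growth-related gene (AT3G16640, chromosome 3, 5669317 to 5670842), with 5332 ± 865 CPM. The metallothionein gene MT2B (AT5G02380, chromosome 5, 506498 to 507244) had 4814 ± 2123 CPM, and its level ranged from 2164 CPM in core 3 to 6706 CPM in core 1. Photosystem II genes PSBR and PSBO1 had 4558 ± 1124 and 3165 ± 627 CPM, and ESM1, which affects glucosinolate breakdown, had 4462 ± 1643 CPM. EMB2296 had 3262 ± 536 CPM. The genes AT5G42530 and AT1G72610, given by locus identifier, completed the 10 highest, with 4827 ± 1604 CPM and with 1046 to 4277 CPM. The exons of AT1G72610 lie over those of a gene on the opposite strand along 92.2% of their length, so its counts may include reads of its partner. The 10 genes with the most counts in each library, organelle genes included, took 7.08 ± 0.549% of the same counts.

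Among nuclear genes with 1 transcript model, 12803 had at least 10 counts in each of the 4 libraries, and 13250 had at least 1 CPM in each, 12906 of them protein-coding. A total of 1633 genes reached 100 CPM in each library, and 3647 had no count in any. A count of 0 allowed up to 0.409 CPM in core 1, the deepest library, and 0.561 CPM in core 4, the shallowest. Intervals and floors cover counting error only. Organelle genes gave 3.69 ± 1.01% of the counts on genes with 1 model (SD, n = 4), of which 2.82 ± 0.675% came from the chloroplast and 0.868 ± 0.339% from the mitochondrion. The organelle share was 2.94% in core 1 (95% exact binomial interval 2.93 to 2.95%), 3.09% in core 2 (3.08 to 3.10%), 5.15% in core 3 (5.13 to 5.17%) and 3.57% in core 4 (3.56 to 3.59%). The highest organelle genes were ATMG00020 with 5349 ± 1178 and ATCG00340 with 5125 ± 1114 CPM of all counts, and no gene names were matched to these loci. ATMG00020 and ATMG01390 held most of the mitochondrial share in every core. ATMG00020 had 4309, 4991, 7042 and 5053 CPM in cores 1 to 4 and ATMG01390 710, 1407.5, 5238 and 2576 CPM. The mitochondrial share was 0.566, 0.707, 1.35 and 0.854% in cores 1 to 4. Ribosomal and transfer RNA genes of the organelles could not be set apart, so the share is no measure of protein-coding genes. Whole blocks of loci, such as ATCG00830 to ATCG00990 and ATMG00170 to ATMG00550, had no counts in any library. The organelle shares may therefore miss reads, and the cause was not tested.

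Photosynthesis and cell division genes were both highly expressed, while the median levels of the root, pollen and seed lists were below the floor. The 27 measured nuclear photosynthesis genes had a median level of 919.9 CPM per kb (9.85 ± 0.29 on the log2 scale, SD, n = 4), against 4.82 CPM per kb for all nuclear protein-coding genes. That median exceeded those of all 10000 random lists of the same size. LHCB1.3 and LHCB6, another light-harvesting gene (3060 ± 811 CPM), were the highest members per kb, and LHCB2.1 (52.4 to 83.1 CPM) and LHCB2.2 (81.0 ± 12.7 CPM) were the lowest. Reads of the LHCB1, LHCB2 and RBCS families can be shared between near-identical copies, so the split between members is uncertain. The 15 measured cell cycle genes had a median of 43.0 CPM per kb (percentile 99.97), and all 15 reached 1 CPM in every library. CDKA;1, the main cell cycle kinase, had 185 ± 26.0 CPM, and PCNA2, a DNA replication clamp gene, 94.1 ± 9.63 CPM. The lowest members per kb were the mitotic cyclins CYCA1;1 (26.7 ± 1.89 CPM) and CYCB1;1 (31.3 ± 4.25 CPM). The exons of PCNA2 overlap an opposite-strand gene along more than 20% of their length.

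Regulators of the shoot meristem and organ boundaries were detected, with a list median of 8.70 CPM per kb (20 genes, percentile 79.9). PDF1, an epidermal marker of the meristem, had 997 ± 212 CPM, and the homeobox gene STM, which maintains the meristem, had 192 ± 92.7 CPM. LAS, needed for axillary meristems, had 1.22 ± 0.352 CPM. WUS, which marks the organising centre of the meristem, was near the limit of counting, with 1 count in core 1 and none in the others. Among floral transition regulators (15 genes, 8.30 CPM per kb, percentile 68.5) AGL24 was the highest member with 119 to 166 CPM. SPL3 had 55.8 to 80.9 CPM, but its exons are covered to 97.4% by an opposite-strand gene. The florigen gene FT had 0.148 ± 0.122 CPM and its close relative TSF 0.245 ± 0.167 CPM, both below the floor. AP1, which specifies floral meristems, had 11.6 ± 2.26 CPM, and LFY had 3.50 ± 2.01 CPM. Floral organ identity genes had a median of 2.41 CPM per kb (5 genes, percentile 39.2). CRC (3.95 ± 1.88 CPM) and PI (2.94 to 4.31 CPM) were the highest of that list per kb, AP3 had 2.59 ± 1.04 CPM and SUP 0.233 ± 0.0820 CPM. Strigolactone and axillary bud genes had a median of 5.53 CPM per kb (10 genes, percentile 56.7), with D14, the strigolactone receptor (75.3 ± 14.1 CPM), and SMXL7, its repressor target (98.5 ± 11.9 CPM), at the top and BRC2 (8.92 ± 2.59 CPM) and MAX3 (5.38 ± 5.24 CPM) lowest.

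Vascular and epidermal genes were detected, with list medians within the range of random lists of protein-coding genes. Phloem and cambium genes had a median of 21.6 CPM per kb (6 genes, percentile 93.6), from SUC2, the phloem sucrose transporter (74.7 ± 18.8 CPM), and SEOR1 (89.2 ± 15.6 CPM) to HB8 (40.2 ± 8.11 CPM) and SMXL5 (38.1 ± 10.5 CPM). Secondary wall and xylem genes had a median of 5.19 CPM per kb (16 genes, percentile 56.3). Among these XCP2, a xylem protease gene, had 78.1 ± 11.7 CPM and the cellulose synthase gene CESA4 40.1 ± 6.42 CPM, while FRA8 had 2.34 ± 0.413 CPM and NST3, a fibre wall regulator, 0.148 ± 0.122 CPM. Epidermis, cuticle, trichome and stomata genes had a median of 3.71 on the log2 scale of CPM per kb (21 genes, percentile 96.6). LTP1, a lipid transfer protein gene, had 2048 ± 242 CPM and LTPG1 377 ± 62.5 CPM, and GL3, a trichome regulator, had 5.01 ± 0.908 CPM and the guard cell channel gene KAT1 9.37 ± 2.38 CPM. Of 18 root genes, 13 stayed under 1 CPM in every library (median 0.212 CPM per kb, percentile 0.05). SCR (a mean of 61.1 CPM) and SHR (41.8 ± 2.14 CPM), which also act in shoots, were the highest members, FRO2 also reached 1 CPM in every library (3.38 ± 1.81 CPM), NRT2.1 and MYB36 did so in some, and the root hair genes EXPA7 and RHD6 had 0 and 1 count in total. Pollen genes (13 genes, 0.153 CPM per kb) lay below every random list, with 4 at 1 CPM or more in every library and 9 under it in every library. AGP6 (4.79 ± 1.63 CPM) and ANX1 (17.3 ± 6.48 CPM) were the highest members per kb, and GEX2 and VGDH1 had no counts. Seed maturation genes (11 genes, 0.124 CPM per kb, percentile 0.02) had OLEO1 at 0.306 to 2.68 CPM and CRB at 0.462 ± 0.194 CPM, and SESA4 and OLEO2 had no counts.

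**Figure D1:**
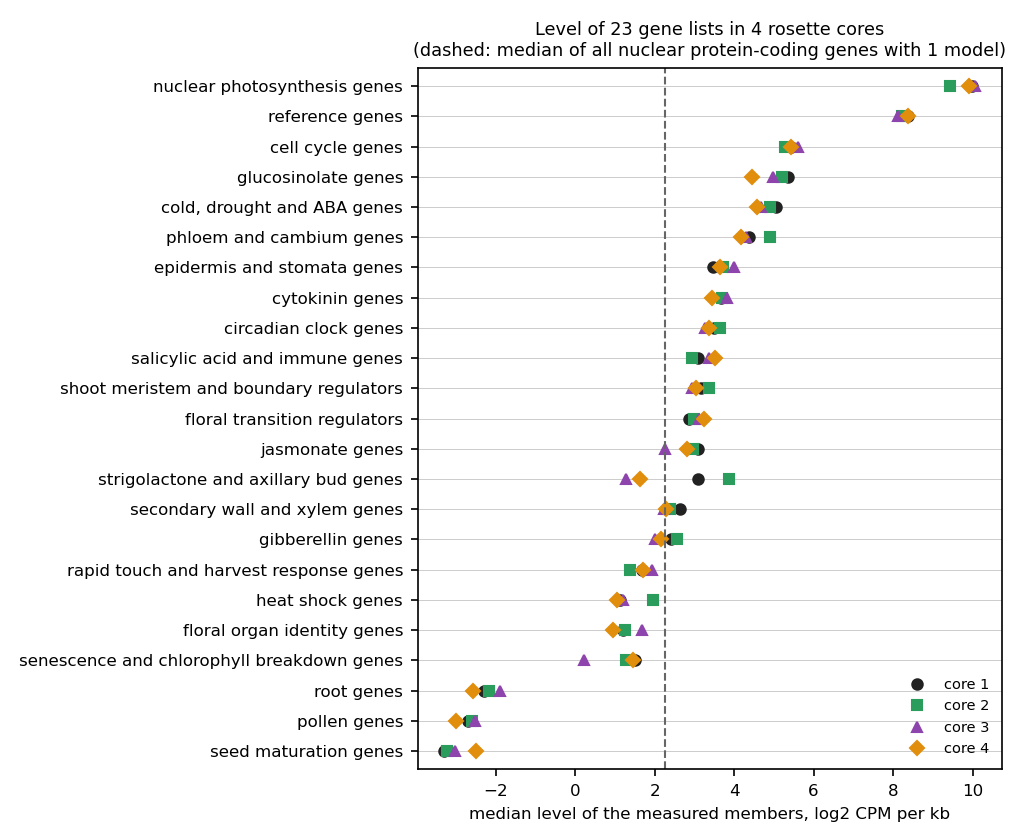
Each point is the median level of the measured members of a gene list in 1 core, in log2 CPM per kb on the horizontal axis, for 23 lists fixed beforehand; the dashed line is the median of all nuclear protein-coding genes with 1 model (4.82 CPM per kb). Photosynthesis genes (9.85 on average) lie at the top and root, pollen and seed maturation genes (-2.24, -2.71 and -3.02) at the bottom in all 4 cores.

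The lists of glucosinolate genes and of cold, drought and abscisic acid genes also had high median levels. With no group to compare, this does not show a response. The random lists come from all nuclear protein-coding genes with 1 model, 36.8% of which had a mean count under 10. A list of genes known to be expressed can thus rank high against them. The glucosinolate list had a median of 31.8 CPM per kb (17 genes, percentile 99.7). CYP83A1, an enzyme of aliphatic glucosinolate synthesis, had 609 ± 204 CPM and BCAT4, which starts methionine chain elongation, 338 ± 213 CPM, while CYP79F2 had 2.67 ± 1.28 CPM and MYB122 0.219 ± 0.283 CPM. The exons of BCAT4 overlap an opposite-strand gene along 21.2% of their length. The cold, drought and abscisic acid list had a median of 27.8 CPM per kb (10 genes, percentile 98.8). KIN2 had 852 ± 587 CPM and RD22 465 ± 79.8 CPM, and KIN1 (3.94 ± 2.61 CPM) and NCED3, an abscisic acid synthesis gene (5.84 ± 5.47 CPM), were lowest. The 5 measured reference genes had a median of 310.1 CPM per kb, above all random lists, with GAPC1 at 1143 ± 65.7 CPM and ACT8 at 723 ± 82.6 CPM at the top and YLS8 at 399 ± 34.9 CPM among the rest; the lowest, AT2G28390 and AT4G34270, had 72.6 ± 6.76 and 63.1 ± 3.19 CPM.

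The other hormone, stress and clock lists lay within the range of random lists. Cytokinin genes had a median of 12.6 CPM per kb (15 genes, percentile 90.2), from the response regulators ARR4 (157 ± 36.2 CPM) and ARR7 (34.1 ± 8.56 CPM) to ARR3 (1.03 ± 0.460 CPM) and IPT7 (0.418 ± 0.355 CPM). Gibberellin genes had a median of 4.87 CPM per kb (14 genes, percentile 50.9), with the DELLA genes RGA (180 ± 19.1 CPM) and RGL1 (124 ± 20.6 CPM) highest and GA20OX2 (0.408 ± 0.374 CPM) and GA3OX2 (0.120 ± 0.0828 CPM) lowest. Circadian clock genes (8 genes, 10.9 CPM per kb, percentile 78.7) ran from ELF4 (34.9 ± 4.68 CPM) and TOC1 (129 ± 13.4 CPM) to PRR7 (21.3 ± 7.63 CPM) and GI (26.2 ± 10.4 CPM). Salicylic acid and immune genes (17 genes, 9.40 CPM per kb, percentile 82.1) ran from WRKY70 (164 ± 47.0 CPM) and PR5 (68.0 ± 28.5 CPM) to FMO1 (0.321 ± 0.335 CPM) and ALD1 (0.180 ± 0.174 CPM). Jasmonate genes (18 genes, 6.85 CPM per kb, percentile 65.6) ran from LOX2 (235 ± 89.9 CPM) and JAZ2 (86.4 ± 16.6 CPM) to JAZ8 (0.375 ± 0.385 CPM) and JAZ7 (0.325 ± 0.311 CPM). Rapid touch and harvest response genes (18 genes, 3.18 CPM per kb, percentile 35.0) had TCH2 (67.2 to 81.5 CPM) and RAV1 (39.8 ± 3.13 CPM) highest and CBF1 (0.417 ± 0.296 CPM) and CBF2 (0.204 ± 0.168 CPM) lowest. The exons of TCH2 overlap an opposite-strand gene along 20.9% of their length. Heat shock genes (8 genes, 2.53 CPM per kb, percentile 36.8) had HSP70 (42.1 ± 13.9 CPM) and HSP101 (17.3 to 24.2 CPM) highest, HSP21 at 0.110 ± 0.0738 CPM and AT4G25200 at no counts. Senescence and chlorophyll breakdown genes (7 genes, 2.16 CPM per kb, percentile 28.3) had PAO (46.1 ± 5.47 CPM) and NYE1 (22.6 ± 3.04 CPM) highest, and SAG12, a marker of late leaf senescence, had 2 counts in core 4 and none elsewhere. Of the 23 lists, 5 lay above and 3 below the central 95% of random lists, where chance puts about 1 list in 20.

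Length-corrected counts of partner genes of related function differed within the same RNA for 12 of the 15 pairs that could be tested, 9 with the first-named and 3 with the second-named gene higher (limma, two-sided, Benjamini-Hochberg over 15 pairs). The p-values cover only the spread of each ratio between libraries. A bias in counting 1 gene that is equal in every library, such as from reads shared between copies, stays outside them. Small ratios may therefore come from such a bias, which was not tested. AP1 exceeded its relative CAL by 2.98 on the log2 scale (SE 0.46, adjusted p = 0.00368 by limma, higher in 4 of 4 libraries). GA20OX1, a gibberellin synthesis gene, exceeded GA20OX2 by 3.79 (SE 0.55, adjusted p = 0.00354 by limma, 4 of 4), although GA20OX2 lay at the floor, so the size depends on the prior count. The gibberellin receptor gene GID1A exceeded GID1B by 2.97 (SE 0.24, adjusted p = 0.000536 by limma, 4 of 4). PSBO1 exceeded PSBO2 by 2.28 (SE 0.12) and the plastocyanin gene PETE2 exceeded PETE1 by 2.56 (SE 0.12), both with an adjusted p of 0.000159 by limma and in 4 of 4 libraries. SPL9 exceeded SPL15 by 1.92 (adjusted p = 0.000272 by limma, 4 of 4), and SPL15 lies entirely under exons of an opposite-strand gene. The cyclin gene CYCD3;1 was higher than CYCD3;3, by a log2 ratio of -1.44 of the latter over the former (adjusted p = 0.00128 by limma, 4 of 4), and MYB34 was higher than MYB51 (log2 ratio of MYB51 over MYB34 -1.50, adjusted p = 0.00354 by limma, 4 of 4).

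STM exceeded its fellow meristem gene KNAT1 by 0.50 (adjusted p = 0.0366 by limma, 4 of 4 libraries), and RGA exceeded GAI (log2 ratio of GAI over RGA -0.48, adjusted p = 0.0393 by limma, 4 of 4). The strigolactone synthesis gene MAX4 exceeded MAX3 by 1.24 (adjusted p = 0.0301 by limma, 4 of 4), and CYP83A1 exceeded CYP83B1, its counterpart in indole glucosinolate synthesis, by 1.03 (adjusted p = 0.0206 by limma, 4 of 4). These 4 calls were lost in part of the alternatives. The STM call was lost without any 1 core (0.40 to 0.60) and with no length term (0.26), the MAX4 call without core 1, 2 or 3 (1.21, 1.12 and 1.00), the CYP83A1 call without core 1, 2 or 4 (0.92, 0.87 and 1.03), and the GAI call without core 1, 2 or 3 (-0.43, -0.39 and -0.54) and with no length term (-0.41). The boundary genes CUC2 and CUC1 had a log2 ratio of 0.73 (adjusted p = 0.121 by limma, CUC2 higher in 4 of 4 libraries) and PR2 was 2.14-fold PR1, another defence gene (adjusted p = 0.140 by limma, PR2 higher in 3 of 4), so neither difference passed. PR1 and the jasmonate marker PDF1.2 had a log2 ratio of -2.66 (adjusted p = 0.0978 by limma, PR1 higher in 1 of 4), which passed without core 3 (-3.73) and was -1.88 without core 1 and -1.80 without core 2, not past the threshold. Of the 35 pairs fixed, 18 had both genes with 1 transcript model, and 3 of these were below the count minimum. The other pairs, among them SOC1 with FLC and CCA1 with LHY, were not analysed here.

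**Figure D2:**
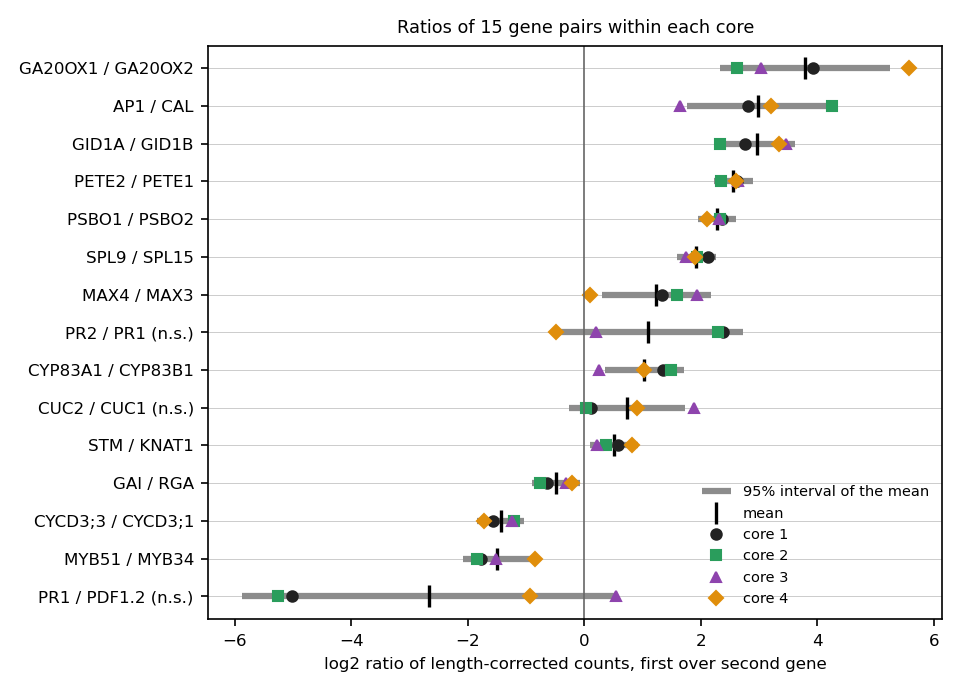
Log2 ratio of the length-corrected counts of 2 partner genes (first over second, horizontal axis) for 15 pairs, with 1 point per core, the mean as a black tick and its 95% interval from limma as a grey bar; n.s. marks the 3 pairs that did not pass. PSBO1 over PSBO2 lay between 2.31 and 2.36 in cores 1 to 3, while PR1 over PDF1.2 ran from -5.25 in core 2 to 0.54 in core 3.

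The 4 cores differed by more than counting noise, and glucosinolate genes spread more than matched random lists by both measures used, also without any 1 core. Leaving out 1 core keeps their split of cores 1 and 2 from cores 3 and 4 in place. Of 12771 nuclear genes tested, 8200 (64.2%) varied between libraries beyond counting noise (chi-square test of counts, Benjamini-Hochberg adjusted). Of 225 fixed list members among them, 172 varied beyond counting noise, and 174 with the p-value adjusted over the list alone. Separate samples exceed counting noise by default, and abundant genes do so most readily, so these counts do not set a list apart. Pearson's r between libraries, across genes, ranged from 0.940 (cores 2 and 3) to 0.981 (cores 1 and 2) with a mean of 0.964. Genes are not independent replicates, so r describes these libraries only. The common biological coefficient of variation was 21.1% (edgeR). No library pair agreed within counting noise, the chi-square per gene ranging from 11.1 to 42.6.

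The glucosinolate list differed between cores: its median deviation from the mean of the 4 cores was 0.26, 0.31, -0.38 and -0.28 (log2) in cores 1 to 4, a range above every one of the expression-matched random lists. Cores 1 and 2 thus lay on 1 side and cores 3 and 4 on the other, as on the first principal component described below. Leaving out 1 core keeps both sides, so it does not test whether the result rests on this split. BCAT4 had 478, 549, 89.8 and 237 CPM in cores 1 to 4, MAM1 226, 251, 82.7 and 124.8 CPM, and CYP83A1 771, 782, 362 and 523 CPM. Other members did not follow this order: CYP79B3 was highest in core 3 (96.8 CPM) and lowest in core 4 (48.5 CPM), MYB34 was also highest in core 3 (30.6 CPM), MYB51 had 5.31, 6.99, 10.7 and 9.80 CPM, and CYP83B1 stayed between 256 and 302 CPM. Of the 15 members tested, 13 varied beyond counting noise, and 13 adjusted over the list alone. Photosynthesis genes deviated by 0.09, -0.40, 0.27 and -0.01 in cores 1 to 4 (percentile 100), with all 27 beyond counting noise, also adjusted over the list alone. The Calvin cycle gene GAPA had 2404, 1808, 3695 and 3021 CPM and LHCB6 2912, 2038, 3978 and 3313 CPM, while LHCA4 (1422, 1191, 1394 and 1086 CPM) and LHCB1.4 (560.4, 366, 443 and 285 CPM) were lowest in core 4. Meristem and boundary genes deviated by 0.08, 0.44, -0.24 and -0.14 (percentile 99.99, but 90.05 without core 2), and 12 of 14 tested members varied beyond counting noise, as they did adjusted over the list alone. STM had 194, 317, 95.8 and 163 CPM and KNAT1 153, 289, 97.1 and 109 CPM, while CLV1, a meristem receptor gene, had 81.9, 92.0, 104 and 74.1 CPM.

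Cold, drought and abscisic acid genes deviated by 0.24, 0.33, -0.17 and -0.35 in cores 1 to 4 (percentile 99.8, but 97.05 without core 4, with all 8 tested members beyond counting noise, also adjusted over the list alone). KIN2 had 1354, 1366, 316 and 372 CPM, while RD22 had 400.3, 560.1, 503 and 398 CPM. Salicylic acid and immune genes deviated by 0.00, -0.40, -0.04 and 0.20 (percentile 99.95, 9 of 13 beyond counting noise, also adjusted over the list alone), but the percentile was 93.6 without core 2 and 87.95 without core 4. PR5 had 68.9, 30.0, 74.3 and 98.8 CPM. PR1, a marker of salicylic acid responses, had 18, 9, 189 and 189 counts in cores 1 to 4, but was not among the genes tested because its counts in core 2 were under the minimum. Phloem and cambium genes (percentile 99.6, 6 of 6 beyond counting noise), epidermal genes (99.7, 17 of 20) and cytokinin genes (99.1, 12 of 12) also spread more than matched random lists, with the same numbers adjusted over the list alone. Without core 2 the percentile was 91.35 for phloem and 95.6 for epidermal genes, without core 4 it was 97.25 for phloem and 66.55 for cytokinin genes, and without core 1 it was 89.45 for cytokinin genes. The cambium receptor gene PXY had 79.8, 141, 95.1 and 74.7 CPM, and TMM, a stomatal patterning gene, 81.9, 37.2, 92.7 and 69.2 CPM. The median of the 10 strigolactone genes was 3.10, 3.86, 1.29 and 1.62 log2 CPM per kb in cores 1 to 4, the largest spread of the 23 lists. The shift measure covers only 6 of them (percentile 92.2, 5 of 6 beyond counting noise, also adjusted over the list alone), as MAX4, MAX3, HB40 and HB53 did not pass the filter on low counts in core 3, so it does not decide for the list. It exceeded random lists without core 3 (percentile 100, range 1.02 instead of 0.47) and without core 2 (99.2). The members that pass the filter can change when a core is left out, so these ranges may not cover the same genes. MAX4 ran from 1.38 CPM in core 3 to 37.8 CPM in core 2, and the bud dormancy gene HB21 had 13.6, 19.9, 2.76 and 3.58 CPM in cores 1 to 4.

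Most other lists did not stand apart in this measure. Cell cycle genes (percentile 93.5, 13 of 15 beyond counting noise), clock genes (94.98, 6 of 8), gibberellin genes (90.4, 6 of 10), secondary wall genes (88.1, 7 of 14), touch response genes (78.7, 3 of 12), jasmonate genes (71.8, 10 of 13), senescence genes (68.9, 2 of 3), floral transition regulators (52.8, 6 of 12), heat shock genes (48.5, 1 of 4), floral organ genes (33.4, 1 of 3) and root genes (10.7, 2 of 3) lay within the range of random lists. Adjusted over the list alone, the number became 8 for the clock list, 3 for the senescence list and 2 for the touch list, and was equal for the others. Pollen genes had 2 members tested, both beyond counting noise and so adjusted over the list alone, and seed maturation genes none. Reference genes spread little (percentile 1.02, 4 of 5 beyond counting noise, also adjusted over the list alone), though the percentile was 10.5 with library totals and 8.6, 11.3 and 20.4 without core 1, 3 or 4, and GAPC1 had 1182, 1165, 1046 and 1181 CPM. The number of lists above the central 95% of random lists was 8 of 21, falling to 5 without core 2 and to 4 without core 4. Only photosynthesis and glucosinolate genes stayed above it when any 1 core was left out. Even so, the photosynthesis range fell from 0.66 to 0.25 log2 without core 2, and the glucosinolate range from 0.70 to 0.49 without core 1. The shift measure was chosen after the counts were seen.

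**Figure D3:**
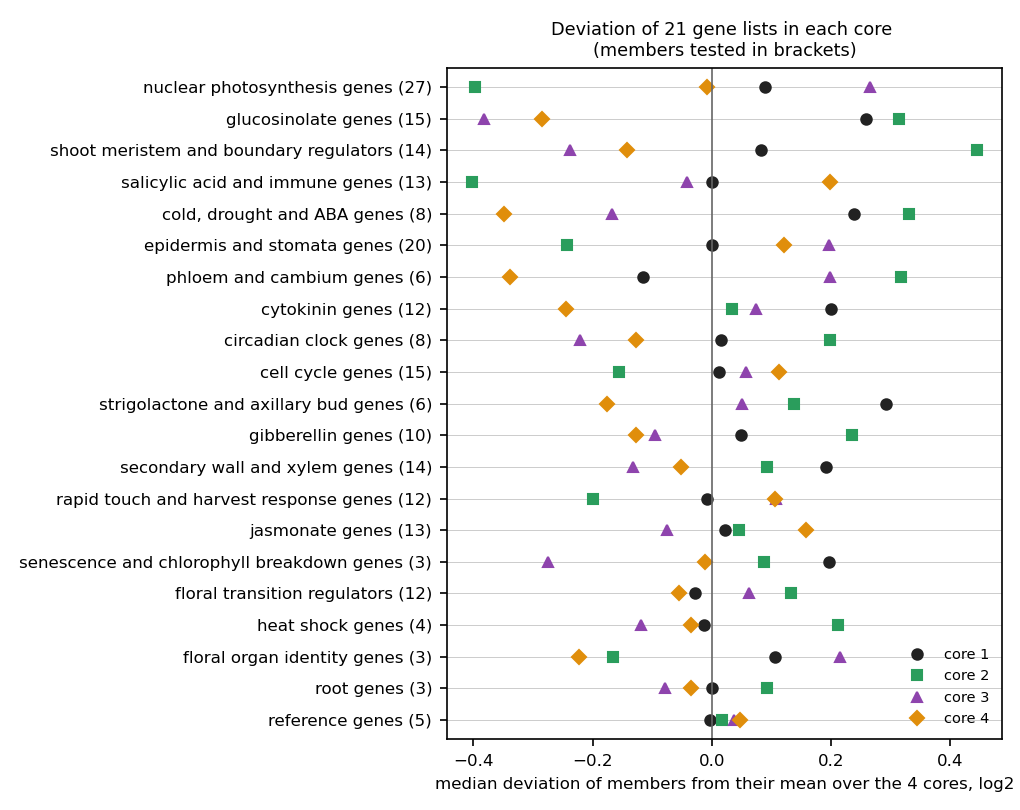
Median deviation of the tested members of 21 gene lists from their mean over the 4 cores, on the log2 scale, with 1 point per core. Glucosinolate genes run from -0.38 in core 3 to 0.31 in core 2 and photosynthesis genes from -0.40 in core 2 to 0.27 in core 3, while reference genes stay within 0.05 of 0.

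No gene was more variable than genes of the same level by edgeR's quasi-likelihood test at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 677 genes, DESeq2 marked 70 as dispersion outliers, and the edgeR test with no filter on low counts called 431. On simulated counts with the gene-specific scatter of these libraries the edgeR test recovered 0% of genes raised 16-fold in 2 of the 4 libraries. It could not have found such genes, and a change in 1 library alone was not simulated. In the order of the ratio of quasi-dispersion to trend, and so named after their values were seen, the gene AT3G01345 (chromosome 3, 129138 to 130749) came first with 18.18, 42.5, 638 and 82.4 CPM in cores 1 to 4. AT2G39870 had 2.66, 1.64, 67.1 and 57.9 CPM. UMAMIT36, of a family of amino acid transporters, had 128, 173, 3.98 and 43.0 CPM, and the sucrose synthase gene SUS4 102, 168, 6.43 and 46.8 CPM. LTP4, a lipid transfer protein gene, had 561, 1629, 219 and 123 CPM, ARD3 67.4, 30.0, 89.2 and 345 CPM, DR4 99.7, 169, 16.7 and 41.1 CPM, and KTI1, a protease inhibitor gene, 33.1, 45.8, 2.91 and 7.73 CPM. The genes AT5G10770, AT5G37970, AT4G33070 and AT1G19550 completed the 12, with ratios of the highest to the lowest library of 12.8, 12.01, 16.1 and 14.7. AT1G19550 lies wholly under exons of an opposite-strand gene. By the planned measure, the ratio of quasi-dispersion to trend, glucosinolate genes reached percentile 100 of matched random lists, epidermal genes 99.8, jasmonate genes 99.2, cytokinin genes 99.1, cold-response genes 98.99, phloem genes 98.9, photosynthesis genes 98.6 and meristem genes 98.4, while salicylic acid and immune genes (86.3) lay within the range of random lists. Only the glucosinolate list stayed above the central 95% of random lists without any 1 core, and the number of lists was 5 without core 1, 3 without core 2 and 5 without core 4.

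**Figure D4:**
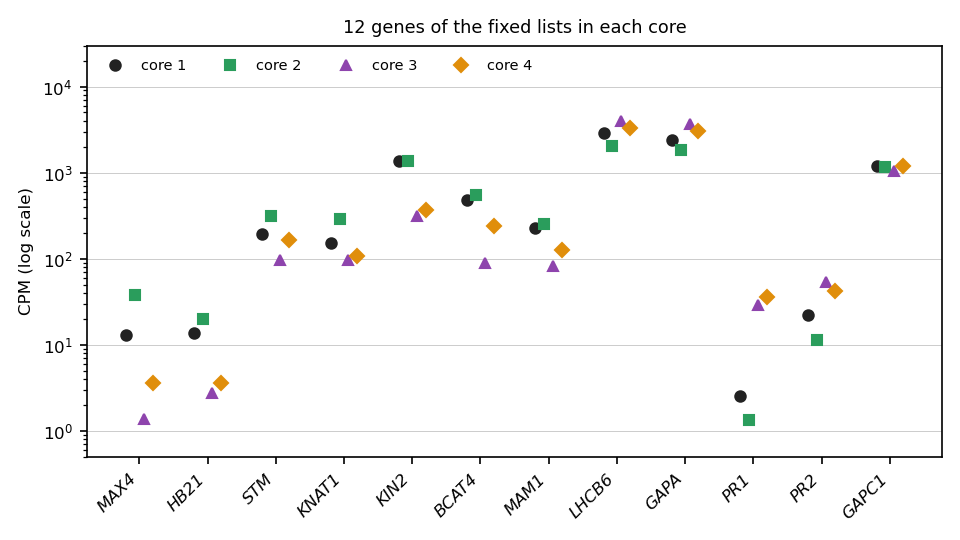
CPM on a log axis of 12 genes of the fixed lists, chosen after their values were seen, with 1 point per core. MAX4 ran from 1.38 CPM in core 3 to 37.8 CPM in core 2 and PR1 from 1.34 CPM in core 2 to 35.6 CPM in core 4, while GAPC1 stayed between 1046 and 1182 CPM.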

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

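Both tests of the uncounted transcript models, the test of reads assigned to both strands and the test of leaf and apex shares were chosen after the results were seen; the other tests in this part were written before.

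In 15 of 205 groups of 4 values, 1 core stood far from the other 3. A rate of 1 in 20 would give 10.2, but that rate holds for independent normal values only. The groups overlap and include values near 0 counts and genes picked for their spread. The number 15 therefore shows neither an excess over chance nor its absence. In core 3 the senescence list had a low median level (0.23 log2 CPM per kb, against 1.28 to 1.50), CESA4 was low (30.5 CPM), as were RAV1 (35.1 CPM), GAPC1 (1046 CPM) and CYCD3;1 (112 CPM), and AT3G01345 was high (638 CPM). Only 3 of the 7 measured senescence genes reached 1 CPM in every library. The 3 tested for shifts deviated by -0.27 log2 in core 3, and their range over cores lay at percentile 68.9 of random lists. In core 2 the epidermal genes PDF1 (682 CPM) and LTPG1 (283 CPM) were low, as was the ratio of PETE2 over PETE1 (2.35 log2). In core 1 JAZ2 was high (111 CPM), and in core 4 PSBO1 over PSBO2 was low (2.101 log2). WUS in core 1 (0.140 CPM), RHD6 in core 3 (0.153 CPM), HSP21 in core 4 (0 CPM) and SAG12 in core 4 (0.377 CPM) stood apart by no more than 2 counts. Rows of genes with several transcript models, outside every comparison above, held 1.67% of all counts.

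Genes with several transcript models had counts near 0, among them ACT2 and UBQ10, which are used as controls because they are expressed throughout the plant. Of 6 such reference genes 1 reached 10 CPM, against 5 of 5 with 1 model, which argues against weak expression as the cause. Models with at least 300 bases of their own had a mean count of at least 10 in 26.1% of 1873 cases, against 1.65% of 3750 models with none, consistent with reads shared between models of a gene having been left unassigned. The samples form 1 group, so no biological explanation resting on a difference between groups was tested here or below.

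Genes on opposite strands that cover each other by at least 80% had counts within 1.5-fold in 74.2% of 31 pairs, against 7.60% of 4839 neighbouring pairs with no overlap (Fisher's exact test, two-sided, p = 1.5e-19). Both sets hold pairs with at least 200 counts in the higher gene. This may come from reads of 1 transcript counted for both strands. Independent sense and antisense transcripts are argued against by the ratio within a pair, which differed between libraries in 6.45% of the pairs (chi-square test, adjusted), against 68.5% of 1572 neighbours without overlap. These neighbours had at least 200 counts in the lower gene too, a limit not set on the overlapping pairs, so the shares were not measured at like counts. The kit marks strand, but how strand was used in the counting is not given in the sources used here.

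The first principal component held 65.9% of the variance between cores, with scores of -19.5, -33.3, 36.9 and 15.9 in cores 1 to 4. It kept 101.3% of its variance after every library was thinned to the smallest total, 91.5% after trends with GC content and exon length were removed, and 99.2% without the 100 most abundant genes, which argues against depth, these biases and a few abundant genes as the whole cause. Different shares of leaf and apex tissue stay open: from core 2 to core 3 photosynthesis genes differed by 0.71 log2 (bootstrap interval over members 0.40 to 0.86) and meristem genes by -0.74 (-1.32 to 0.17). Cell cycle genes, which a smaller apex share would lower too, exceeded the meristem list by 0.94 in this difference, but the interval (-0.11 to 1.48) includes 0. These intervals cover the spread between list members only, and members are not independent replicates. They do not cover the spread between cores, and cores 2 and 3 were picked as the ends of the component. Differences between plants, in harvest or in batch were not tested and stay open, as the labels number the cores C2, C4, C10 and C12 without saying what the numbers mark. Glucosinolate, cold and meristem genes also had higher median deviations in cores 1 and 2 than in cores 3 and 4. These lists divide the cores as the component does, so they need not be separate findings.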

How the results depend on the processing

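No paired analysis was possible because the samples form 1 group. The count of genes more variable than genes of the same level went from 0 to 431 with no filter on low counts and to 70 by DESeq2's dispersion outliers, and stayed 0 under the other settings run. The cause was not tested. Leaving out 1 core moved the number of lists above the central 95% of random lists from 8 to between 3 and 9 for variability and to between 4 and 9 for shifts, the latter a measure added after seeing the data, so both rest on which cores are included. Of 71 alternative values of the main results 64 stayed within limits, among them 6468 to 8482 genes beyond counting noise, 11028 to 13970 genes detected by CPM, an organelle share of 3.20 to 3.94%, 8 or 9 lists of extreme level and 8 to 12 gene pairs. The 8 lists of extreme level also kept their side without any 1 core. Of 12 gene pairs 8 kept their call in all 7 alternatives. No value changed sign. Of 46 list medians recomputed without length or without overlapping genes, 21 moved by over 1 SD. The organelle alternative without ribosomal and transfer RNA genes was not run. Depth limits the lists of root, pollen and seed genes, most of whose members lie under the floor.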

Other observations

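The genes described here were chosen after their values were seen. DFR, an anthocyanin synthesis gene that makes leucoanthocyanidins, had 660.1, 872, 135 and 415 CPM in cores 1 to 4 and the glycosyltransferase gene UF3GT 95.1, 147, 17.5 and 97.1 CPM. DMR6, a negative regulator of immunity, had 42.5, 14.7, 73.5 and 128 CPM, HR4 4.33, 7.29, 47.0 and 21.9 CPM, the receptor-like gene RLP41 4.61, 1.93, 24.7 and 19.0 CPM and SNC4 5.31, 6.54, 35.4 and 27.1 CPM. All 6 varied beyond counting noise, as did 64.2% of all genes tested, so they stand for no group of genes, and none passed edgeR's quasi-likelihood test after adjustment. The nitrate transporter gene NRT2.1, listed as a root gene, had 8.25, 12.6, 0.153 and 1.89 CPM.

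AT5G02370, which lies beside MT2B on the opposite strand (chromosome 5, 503408 to 505982) without overlap in the reference used here, had 3816, 4294, 1499 and 2435 CPM in cores 1 to 4, while MT2B had 6706, 6341, 2164 and 4045 CPM.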
